A study of Mus musculus with 2 samples.

How the data were processed

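Single-cell RNA libraries were made from CD45-sorted MC38 tumour cells with a 3′ droplet assay, and mice were pooled after cell hashing, per the labels' protocols. The GEO samples are the 2 parts, gene expression and hashtags, of library 2, said by the labels to hold mice 7 to 12. The deposited counts are UMI counts per feature and droplet from Cell Ranger 9.0.0, per the file headers, on a combined human GRCh38 and mouse GRCm39 build, per the submitters' processing notes. The matrix is unfiltered, with 2979617 barcodes and 72308 features (38606 human, 33696 mouse, 6 hashtag). A deposited table gives the authors' treatment, cell type and cluster for 19210 cells; how these were assigned, and how doublets were treated, is not given in the sources used here, and no doublet caller was run. The unannotated barcodes with at least 500 UMIs numbered 5815 of 16291.

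The annotation does not name mice. Its barcodes fall into 12 runs of sorted barcodes, each with 1 treatment, which were taken as the 12 mice. In library 2 the hashtag counts checked this for 10476 of 10476 cells. In library 1, whose matrix was not analysed here, the mice rest on these runs alone. Replicates are numbered in the order of the runs within a treatment. Each mouse is the replicate; cells are not. Total UMIs in annotated cells of library 2 ran from 1.72e+07 to 2.58e+07 per mouse. Human features held 0.591% of UMIs. Median mitochondrial percentages per mouse lay between 1.49% and 2.00%, and 0 cells were over 10%.

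Cell types follow the deposited annotation and were checked against markers fixed before the data were examined, as were the comparisons, the tests, the gene lists, the rule for named genes and the alternatives, except where stated. A cluster counts as led by another class when more markers of that class than of its own stand among its 10 leading genes. Raw counts were summed per mouse and class for macrophages, monocytes, CD8 T cells, NK cells and dendritic cells (4 types summed), over mice with at least 10 cells. They were tested with edgeR 4.0.16 (filterByExpr, TMM, glmQLFit and glmQLFTest) in 1 fit of all 6 mice per class with 2 residual degrees of freedom and Benjamini-Hochberg adjustment within class and contrast; a gene passed at an adjusted p under 0.05. The single N297A mouse and the single Untreated mouse are assumed to vary like the paired treatments. CPM of the edgeR fits are counts per 1e6 UMIs of the genes kept by the filter, scaled by TMM. CPM of receptors and all other CPM are counts per 1e6 mapped UMIs of the cells. Both were computed here. Fold changes are edgeR estimates on the log2 scale. Their SE was computed here as the size of the fold change divided by the square root of the F statistic. Shares per mouse were tested with an exact two-sided permutation of the between-treatment sum of squares within libraries (32400 arrangements), adjusted over 10 types. They were also tested with edgeR on cell counts, in a fit with treatment and library as terms. Gene lists were tested with camera of limma 3.58.1 at a correlation of 0.01, adjusted over lists within class and contrast. They were tested again with an estimated correlation and with fry. With an estimated correlation camera takes its p from the residual degrees of freedom of the fit, 2 per class and 1 for CD4 cells. A list could hardly pass that setting here, so a failure there does not decide about a list. Cells were thinned to 3000 UMIs for shares of cells with a receptor UMI.

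Genes named are, per class and contrast, up to 5 with the highest and 5 with the lowest log2 fold change among those past the threshold whose mice do not overlap, up to 4 members per list with the smallest p, and always Tnfrsf18, Foxp3, Tnfsf18 and the human FCGR genes, trimmed to the order of the rule; where fewer than 5 pass, genes with the smallest p are named as not passing. Not every gene that this rule selects is named. Genes of NK cells and cDC2, C1qa, S100a8 in monocytes, Ikzf2, Areg and Penk, sex-linked genes and genes outside the annotation were chosen after their values were seen.

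The edgeR step was tested on simulated counts with 200 changed genes per class. In monocytes, for GA-aFuc against Untreated, it recovered 27 of 100 genes changed 2 fold and 94 of 100 changed 8 fold. It made 23 false calls over 11920 genes. Beside 27 and 94 true calls, these 23 exceed the share of 0.05 that the adjusted p allows. Calls past the threshold may thus hold more false ones than it states. Over classes and 2 contrasts the step recovered 17 to 61 and 83 to 94 of 100, with 3 to 23 false calls. The share test, on 50 simulated tables with 1 type changed 5 fold, passed in 20, with 7 calls among 450 unchanged types.

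Alternatives were DESeq2 1.42.0, RLE size factors, no filter and a stricter filter on low counts, mouse features only in library sizes, a minimum of 30 cells, equal cells per mouse, cells without the highest 1% of UMIs, fits of the compared treatments alone, each mouse left out, other denominators and strata of shares, and other list tests. Chosen after seeing the data were the contrast of both Fc-enhanced treatments, cDC2 alone, a minimum of 5 CD4 cells, sex as a covariate, shares centred within libraries, classes without clusters led by other markers, Tregs among Tregs and CD4 cells without Cd8a UMIs, and counts of Foxp3 and Cd8a UMIs. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3. Coordinates are not given, since the reference annotation at hand is of another build.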

Results

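Leukocytes of MC38 tumours, a transplantable mouse colon adenocarcinoma line, were profiled by droplet-based single-cell RNA sequencing after sorting for CD45, a surface marker shared by leukocytes. The tumours grew under the skin of mice that carry human Fcγ receptors, the cell-surface receptors that bind the constant (Fc) part of IgG. Mice received 100 µg of an antibody to mouse GITR with a human IgG1 constant region, in 2 injections 3 days apart, or PBS. They were sampled 4 days post treatment. GITR, encoded by Tnfrsf18, is a costimulatory receptor of the TNF receptor family that is abundant on regulatory T cells (Tregs). The deposited annotation names 4 treatments with 3 mice each: Untreated, N297A (called agonist and Fc-null), GA-aFuc (called agonist and Fc-enhanced) and GITR/Syn GA-aFuc (called non-agonist and Fc-enhanced). The series title asks how an Fc-optimised GITR antibody acts on CD4 T cells and dendritic cells.

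The annotation held 19210 cells in 10 cell types and 58 clusters, from 2 hashed libraries. Library 1 held 8734 of these cells from 6 mice (1 GA-aFuc, 1 GITR/Syn GA-aFuc, 2 N297A and 2 Untreated). It entered comparisons of cell shares only, since its matrix was not analysed here. Library 2 held 10476 cells with counts from 6 mice: 2 GA-aFuc mice (1723 and 1540 cells), 2 GITR/Syn GA-aFuc mice (1729 and 1925 cells), 1 N297A mouse (1791 cells) and 1 Untreated mouse (1768 cells). A cell of library 2 held a median of 12075 unique molecular identifiers (UMIs; range 819 to 31460) and 3507 genes. Mouse medians lay between 10461 and 13084 UMIs. In all 10476 cells the most frequent hashtag was the one of the assigned mouse, with a median of 96.3% of the hashtag counts. Xist, the RNA that coats the inactive X chromosome, stood at 567 and 551 CPM in 1 GA-aFuc and 1 GITR/Syn GA-aFuc mouse. It stood at 1.64 to 1.98 CPM in the other 4 mice, whose Y-linked Uty stood at 55.0 to 71.3 CPM. Both sexes were thus present, which the labels do not state.

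Tregs, the Foxp3-dependent suppressive CD4 T cells, made up far fewer of the leukocytes after the Fc-enhanced antibodies. They were 0.130% ± 0.0732 of annotated cells in GA-aFuc mice and 0.109% ± 0.0937 in GITR/Syn GA-aFuc mice, against 1.18% ± 0.652 in N297A mice and 0.738% ± 0.115 in Untreated mice (SD, n = 3 each). These means rest on 6, 5, 53 and 35 Tregs in all. The 4 treatments differed in an exact two-sided permutation test stratified by library (p = 0.00111, adjusted p = 0.0111 over 10 cell types). The highest share in an Fc-enhanced mouse was 0.217% and the lowest in the remaining mice was 0.447%. Set together after the data were seen, the 6 Fc-enhanced mice averaged 0.120% and the other 6 mice 0.960% (exact p = 0.00444, the smallest that the 225 arrangements allow). The gap was present within each library, with 0.213% against 1.17% in library 1 and 0.0727% against 0.534% in library 2. Among Tregs and CD4 cells together, Tregs were 9.66% ± 1.39 in GA-aFuc mice, 15.6% ± 5.09 in GITR/Syn GA-aFuc mice, 51.9% ± 11.6 in N297A mice and 50.2% ± 8.72 in Untreated mice (SD, n = 3). This fraction depends on which cells count as CD4 cells. Without CD4 cells that carried UMIs of Cd8a, the CD8 α chain, left out in library 2 after the data were seen, it was 25% and 9.09% in the GA-aFuc mice, 12.5% and 16.7% in the GITR/Syn GA-aFuc mice, 42.1% in the N297A mouse and 57.9% in the Untreated mouse. In an edgeR test of cell counts, Tregs fell by 2.12 ± 0.43 (log2, SE) from Untreated to GA-aFuc mice (adjusted p = 0.00397). They fell by 2.68 ± 0.41 from N297A to GA-aFuc mice (adjusted p = 0.000337). They fell by 2.42 ± 0.44 from Untreated to GITR/Syn GA-aFuc mice (adjusted p = 0.00168). N297A against Untreated mice did not pass the same test (0.57 ± 0.28, adjusted p = 0.313). Neither did GITR/Syn GA-aFuc against GA-aFuc mice (-0.31 ± 0.59, adjusted p = 0.791). The exact test of 4 treatments missed the threshold without Untreated replicate 2 (adjusted p = 0.0611) or 3 (0.175) and without the library stratum (0.246). The same test missed it with shares centred within each library, a setting chosen after the data were seen (adjusted p = 0.0914). In library 2 alone its adjusted p was 0.222, the smallest that the 180 arrangements allow for 1 type alone, so that this setting could not pass. Across settings of that exact test the adjusted p ranged from 0.0099 to 0.246. Pairwise exact tests cannot pass here, since their smallest p is 0.111 or 0.167.

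**Figure D1:**
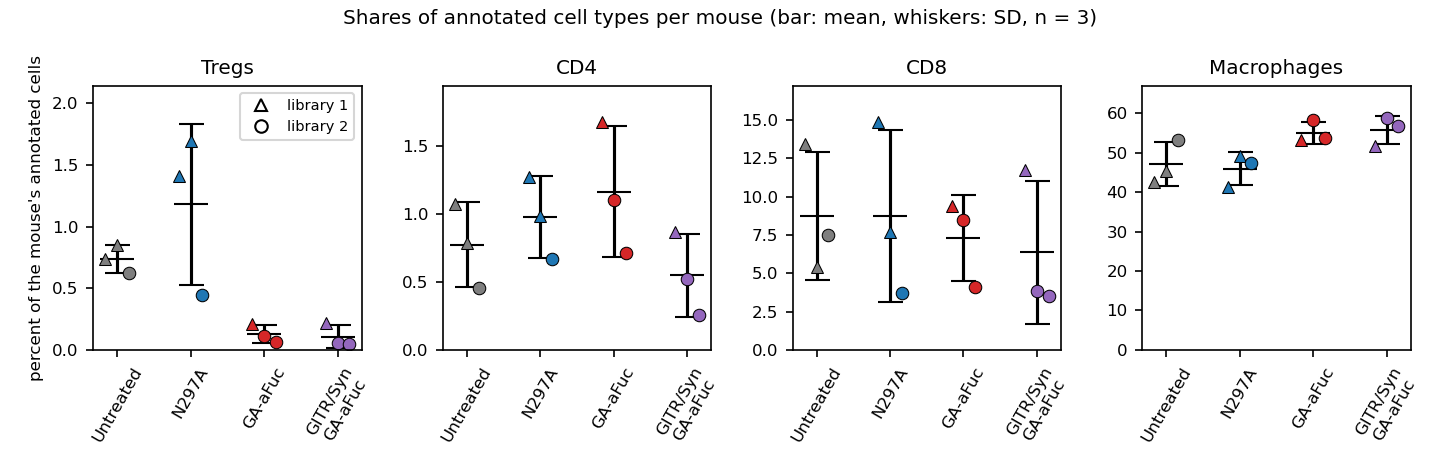
Percent of annotated cells (vertical axes) that were Tregs, CD4 T cells, CD8 T cells or macrophages in each of 12 mice, by treatment (horizontal axes), with triangles for library 1, circles for library 2 and bars for the mean and SD (n = 3). Tregs lie at or below 0.217% in the 6 mice given an Fc-enhanced antibody and at or above 0.447% in the other 6 mice.

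Macrophages, the most frequent cell type, were 55.1% ± 2.78 of cells in GA-aFuc, 55.7% ± 3.60 in GITR/Syn GA-aFuc, 45.9% ± 4.08 in N297A and 47.0% ± 5.60 in Untreated mice (SD, n = 3). In the exact test of 4 treatments this difference missed the threshold (p = 0.0131, adjusted p = 0.0654). It passed that test only without N297A replicate 2 (adjusted p = 0.0463). Set together after the data were seen, the Fc-enhanced mice averaged 55.4% and the other mice 46.5% (exact p = 0.00444, adjusted p = 0.0222). The mice overlapped, with a lowest Fc-enhanced share of 51.7% and a highest other share of 53.3%. By edgeR on cell counts this contrast did not pass (adjusted p = 0.216). Macrophage clusters 12, 25, 39 and 45 (278, 244, 142 and 123 cells of library 2) and monocyte cluster 42 (135 cells) met the rule for clusters led by another class. The rule is weak for macrophages. Clusters 12, 39 and 45 held 1 marker of another class and 0 of their own among 10 genes. The macrophage class as a whole held the same numbers, so these cells are not shown to be mislabelled. Without these clusters the macrophage shares were 52.0% ± 3.20, 52.5% ± 4.41, 43.0% ± 4.59 and 44.1% ± 5.32 (SD, n = 3, adjusted p = 0.0951 by the exact test of 4 treatments). Monocytes held 26.4% ± 7.05, 28.2% ± 3.30, 31.0% ± 4.60 and 30.8% ± 5.38 in the same order of treatments. CD8 T cells held 7.31% ± 2.82, 6.36% ± 4.65, 8.75% ± 5.62 and 8.75% ± 4.16. NK cells, innate cytotoxic lymphocytes, held 6.53% ± 3.05, 4.86% ± 0.880, 8.12% ± 1.14 and 8.50% ± 2.26. The exact tests did not pass for monocytes (adjusted p = 0.772), CD8 T cells (0.805), NK cells (0.252), cDC1 (0.418), cDC2 (0.349), mregDC (0.252) or pDC (0.418). CD4 T cells, without Tregs, were 1.16% ± 0.484 of GA-aFuc, 0.550% ± 0.306 of GITR/Syn GA-aFuc, 0.977% ± 0.303 of N297A and 0.772% ± 0.313 of Untreated cells (SD, n = 3, exact adjusted p = 0.252). By edgeR on cell counts they were higher in GA-aFuc than in Untreated mice (0.91 ± 0.28 log2, adjusted p = 0.0398). They were lower in GITR/Syn GA-aFuc than in GA-aFuc mice (-1.11 ± 0.29, adjusted p = 0.0246). The same test did not pass for CD4 cells in GA-aFuc against N297A mice (0.55 ± 0.27, adjusted p = 0.343) or for any difference between the 4 treatments (adjusted p = 0.0523). In library 2, 14 of the 30 CD4 cells of GA-aFuc mice carried UMIs of Cd8a. This compares with 2 of 14 cells of GITR/Syn GA-aFuc mice and 1 of 20 cells of the other mice.

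GA-aFuc against Untreated was the main comparison of expression, and its clearest change was in monocytes. Arg1 (ENSMUSG00000019987), arginase 1, consumes arginine and marks suppressive myeloid cells. It stood at 1181 and 2246 CPM in monocytes of the GA-aFuc mice and at 165 CPM in the Untreated mouse (log2 fold change 3.38 ± 0.38 SE, adjusted p = 0.00737). Mrc1, the mannose receptor, rose by 3.42 ± 0.51 (135 and 232 against 17.1 CPM, adjusted p = 0.0243). Ccl24, a chemokine for eosinophils, rose by 6.45 ± 1.08 (106 and 628 against 4.17 CPM, adjusted p = 0.0442). Pdcd1lg2, which encodes the PD-1 ligand PD-L2, rose by 2.62 ± 0.32 (95.1 and 129 against 18.2 CPM, adjusted p = 0.0116). Mmp12, the macrophage elastase, rose by 2.75 ± 0.31 (257 and 177 against 32.1 CPM, adjusted p = 0.00737).

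Of 11920 genes tested in monocytes with edgeR, 21 were higher and 0 lower in GA-aFuc than in Untreated mice. The same fit had 783 genes at an unadjusted p under 0.05, and 33 genes were called by DESeq2 (32 higher, 1 lower). In simulated counts of this class the edgeR step made 23 false calls, so some of the 21 calls may be false. Other members of the called set were Hbegf, an EGF receptor ligand (3.65 ± 0.49), Cdh1, E-cadherin (3.45 ± 0.44), and Ksr2, a scaffold of the MAP kinase pathway (3.44 ± 0.59). They also included Fabp5, a fatty acid-binding protein (1.55 ± 0.24), Ccdc162 (1.62 ± 0.23), Il1a, the cytokine interleukin 1α (1.39 ± 0.24), Rnf217 (1.30 ± 0.21), and Flt1, a VEGF receptor (1.25 ± 0.21). Without monocyte cluster 42 the count was 32 higher and 0 lower. S100a8, a neutrophil marker, stood at 131 CPM in monocytes of 1 GA-aFuc mouse and at 8.97 CPM in the other. It stood at 3.96 CPM in the Untreated mouse and did not pass the test. Without GITR/Syn GA-aFuc replicate 2, which enters through the shared estimate of spread, 5 of the 13 monocyte genes named here kept an adjusted p under 0.05. With equal numbers of cells per mouse 5 kept it, with the stricter filter on low counts 7, and without the N297A mouse 8. Without that GITR/Syn GA-aFuc mouse Arg1 lay at 3.38 with adjusted p = 0.0501. All 21 genes also had a positive log2 fold change in macrophages (median 2.05, against 2.16 in monocytes), where 0 of them passed by edgeR. Arg1 stood there at 359 and 1406 against 93.0 CPM (3.25 ± 0.74, adjusted p = 1).

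In the remaining classes of the GA-aFuc against Untreated comparison fewer genes passed than in monocytes. These counts depend on the settings. Over 5 classes 27 genes passed by edgeR, against 622 without a filter and 13 with the stricter filter on low counts. Dendritic cells (cDC1, cDC2, mregDC and pDC summed) had 1 gene past the threshold of 8557 tested, with 596 at an unadjusted p under 0.05. This was Capg, an actin-capping protein, at 160 and 208 against 28.3 CPM (2.70 ± 0.30, adjusted p = 0.00979). In cDC2 alone, a class added after the data were seen, 15 genes were higher and 4 lower of 7404 by edgeR, with 1 gene by DESeq2. Macrophages had 0 of 14340 genes past the edgeR threshold (436 at an unadjusted p under 0.05, 7 genes by DESeq2). CD8 T cells had 0 of 8570 (210 at an unadjusted p under 0.05, 0 genes by DESeq2). The smallest p values in CD8 T cells belonged to genes that did not pass, among them Gzmd, a granzyme (3.50), Klra1, an NK receptor (3.39), and Tox, a transcription factor of exhausted T cells (-1.27). In NK cells 3 genes were higher and 2 lower of 9329. Gzmd stood at 1.59 (adjusted p = 0.0163), Ifitm1 at 1.93 (adjusted p = 0.00347), Ifitm2 at 2.01 (adjusted p = 0.000307) and Klra8, the activating receptor Ly49H, at -1.11 (adjusted p = 0.034). With equal numbers of cells per mouse 1 of these 4 calls was kept and with the stricter filter 2. By DESeq2 the calls of Gzmd (adjusted p = 0.377) and Klra8 (0.211) ended, and that of Klra8 ended without GA-aFuc replicate 2 (0.0676).

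Gene lists fixed beforehand described these profiles as groups. In GA-aFuc against Untreated monocytes the inflammatory cytokine and chemokine list was higher (median 0.71 over 16 genes, adjusted p = 4.19e-06 by camera). It had 1 gene called over all genes and 8 higher when adjusted over the list alone, but adjusted p = 0.842 with an estimated correlation. The glycolysis and hypoxia list was higher as well (median 0.40, adjusted p = 5.02e-05, and adjusted p = 0.842 with an estimated correlation, 0 genes over all and 5 adjusted over the list alone). The MHC class II list, genes of antigen presentation to CD4 T cells, was lower (median -0.55 over 11 genes, adjusted p = 7.07e-05, and adjusted p = 0.842 with an estimated correlation, 0 genes adjusted over the list alone). None of the 5 lists called in this class passed with an estimated correlation (smallest adjusted p = 0.842). That setting could hardly pass with the few residual degrees of freedom here, in this class and the others. In macrophages the MHC class II list was lower (median -0.76, adjusted p = 4.52e-07, and adjusted p = 0.683 with an estimated correlation). Lower as well were the type I interferon (median -0.32, adjusted p = 4.52e-07), interferon gamma (-0.44, adjusted p = 6.45e-06) and MHC class I lists (-0.34, adjusted p = 9.04e-05), each with adjusted p = 0.683 with an estimated correlation and 0 genes adjusted over the list alone. T cell transcripts, which mark RNA of other cells, had a median of -0.60 in the same macrophages (adjusted p = 0.00206, and adjusted p = 0.683 with an estimated correlation). The tumour-associated macrophage list had a median of 0.49 in macrophages (adjusted p = 0.027, and adjusted p = 0.683 with an estimated correlation), with 2 of 18 genes adjusted over the list alone. Dendritic cells had a lower proliferation list (median -0.97, adjusted p = 1.52e-07, and adjusted p = 0.607 with an estimated correlation), with 8 of 20 genes lower adjusted over the list alone. CD8 T cells had a lower proliferation list too (median -0.45, adjusted p = 1.12e-05, and adjusted p = 0.748 with an estimated correlation). Mitochondrial transcripts, a sign of RNA quality, were lower in the same CD8 T cells (median -0.24 over 13 genes, adjusted p = 0.02, and adjusted p = 0.748 with an estimated correlation).

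GA-aFuc against N297A sets 2 agonist antibodies side by side that differ in their Fc part. Monocytes again had the most calls. Arg1 rose by 3.54 ± 0.38 (1181 and 2246 against 147 CPM, adjusted p = 0.00169). Slc7a2, a transporter of the arginase substrate arginine, rose by 4.61 ± 0.55 (adjusted p = 0.00335), Mrc1 by 3.95 ± 0.53 (adjusted p = 0.00715) and Ccl24 by 6.33 ± 1.05 (adjusted p = 0.0203). Cd38, an NAD-consuming ectoenzyme, rose by 1.96 ± 0.32 (adjusted p = 0.0194) and Il1a by 1.83 ± 0.25 (adjusted p = 0.00715). Ptgs2, a cyclooxygenase of prostaglandin synthesis, rose by 1.49 ± 0.23 (adjusted p = 0.0168). Plau, the urokinase, fell by 1.10 ± 0.20 (adjusted p = 0.0338). In CD8 T cells Ifitm1, an interferon-induced membrane protein, rose by 2.25 ± 0.25 (1019 and 1112 against 224 CPM, adjusted p = 0.0136). In dendritic cells Plet1, a surface glycoprotein, rose by 2.63 ± 0.30 (264 and 190 against 36.6 CPM, adjusted p = 0.0107). Ccl4, a chemokine for T cells and NK cells, rose by 1.97 ± 0.24 (637 and 911 against 197 CPM, adjusted p = 0.0107), but with equal numbers of cells per mouse this call ended (2.05, adjusted p = 0.0966).

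The edgeR test called 67 higher and 2 lower genes in monocytes in this comparison (1078 at an unadjusted p under 0.05). It called 1 in CD8 T cells, 2 in dendritic cells, 4 in NK cells and 0 in macrophages (463 at an unadjusted p under 0.05, 19 genes by DESeq2). In cDC2 alone it called 29 higher and 13 lower genes, with 0 by DESeq2. Further called monocyte genes were Ksr2 (5.24 ± 0.72), Pcdh7, a protocadherin (4.44 ± 0.76), and Iigp1, an interferon-inducible GTPase (1.16 ± 0.21). So were Klf7 (1.14) and Vegfa, the endothelial growth factor (1.07). Without monocyte cluster 42 the count was 85 higher and 3 lower. The CD8 Ifitm1 call ended without GA-aFuc replicate 2 (2.31, adjusted p = 0.281) or 3 (2.19, adjusted p = 0.356). Without GITR/Syn GA-aFuc replicate 2 the call held for 7 of the 13 monocyte genes named. With equal numbers of cells per mouse it held for 10, and those of Pcdh7 (adjusted p = 0.0544), Vegfa (0.0758) and Klf7 (0.141) ended. By DESeq2 the call of Plau ended (adjusted p = 0.103). Among lists, interferon gamma genes were higher in macrophages (median 0.75 over 21 genes, 3 adjusted over the list alone, adjusted p = 7.49e-07, and adjusted p = 0.813 with an estimated correlation). They were higher in monocytes too (median 0.34, 4 genes over all and 8 adjusted over the list alone, adjusted p = 1.51e-05, and adjusted p = 0.754 with an estimated correlation) and in dendritic cells (median 0.25, adjusted p = 0.0103, and adjusted p = 0.702 with an estimated correlation). The same list was lower in CD8 T cells (median -0.39, adjusted p = 0.00821, and adjusted p = 0.728 with an estimated correlation) and NK cells (median -0.37, adjusted p = 0.00388, and adjusted p = 0.938 with an estimated correlation). Macrophage transcripts, which mark RNA of other cells, had a median of -0.78 in the same NK cells (4 of 8 lower adjusted over the list alone, adjusted p = 0.12 by camera). Type I interferon genes were lower in CD8 T cells (median -0.77 over 23 genes, 6 adjusted over the list alone, adjusted p = 5.15e-09, and adjusted p = 0.678 with an estimated correlation). Cytotoxicity genes were higher in them (median 0.34 over 14 genes, 6 adjusted over the list alone, adjusted p = 0.0104, and adjusted p = 0.678 with an estimated correlation). The naive and memory T cell list was lower in the same cells (median -0.62 over 11 genes, 4 adjusted over the list alone, adjusted p = 0.00918). No list of this class went below adjusted p = 0.678 with an estimated correlation. Dendritic cells had a lower proliferation list (median -0.77, 2 genes adjusted over the list alone, adjusted p = 0.000115, and adjusted p = 0.702 with an estimated correlation). T cell transcripts had a median of -1.22 in them.

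**Figure D2:**
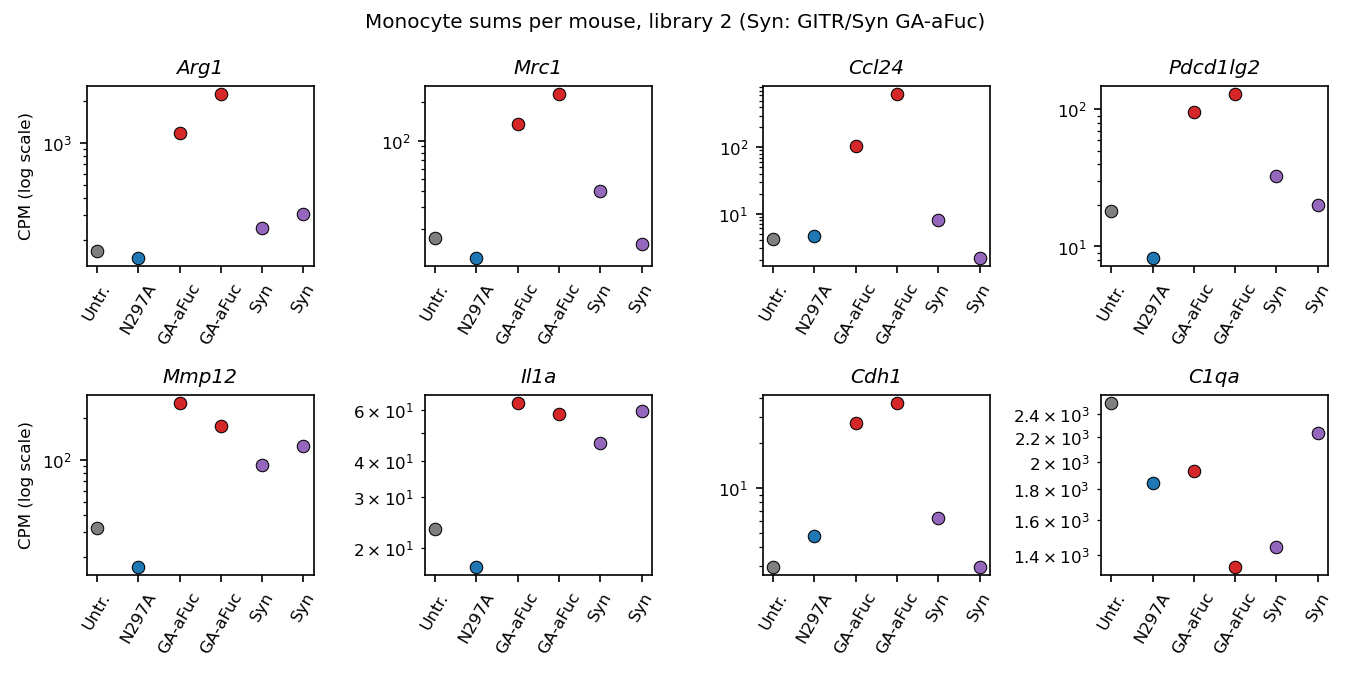
CPM (vertical axes, log scale) of Arg1, Mrc1, Ccl24, Pdcd1lg2, Mmp12, Il1a, Cdh1 and the macrophage gene C1qa in summed monocytes of the 6 mice of library 2, 1 point per mouse, coloured by treatment. Arg1 stands at 1181 and 2246 CPM in the GA-aFuc mice and at 147 to 305 CPM in the other 4 mice.

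CD4 T cells were tested in GA-aFuc against N297A only, because just 3 mice (2 GA-aFuc, 1 N297A) held at least 10 of them. This fit kept 1 residual degree of freedom, which comes from the 2 GA-aFuc mice alone. Gzmb, granzyme B, a protease of cytotoxic cells, was higher in CD4 cells of the GA-aFuc mice (3.31, adjusted p = 0.00267). CD8 cells within this class bear on it, since 13 of 19 CD4 cells of 1 GA-aFuc mouse carried Cd8a UMIs, against 1 of 12 in the N297A mouse. Of the 145 Gzmb UMIs of GA-aFuc mice, 106 lay in the 14 cells with Cd8a UMIs and 39 in the 16 cells without, which stood at 361 CPM against 84.6 CPM in such cells of the N297A mouse. Also higher were Ifitm1 (3.21), the heat-shock genes Hspa1a (8.44) and Hspa1b (7.90), the macrophage transcript Apoe (3.23), Lyn, a kinase of myeloid and B cells (3.38), Ccl12 (3.99) and Ccdc138 (7.24). Tnfsf11, which encodes RANKL (-2.74), Ccl1, a chemokine (-2.49), Aff3 (-2.08) and Dthd1 (-6.30) were lower. In total 13 genes were higher and 4 lower of 2142 by edgeR, with 104 at an unadjusted p under 0.05 and 0 genes by DESeq2. In 14 of these 17 genes over 50% of the UMIs of the higher treatment lay in 1 cell, such as 79 of 80 for Hspa1a and 237 of 294 for Apoe. The list of dissociation stress, a sign of cell handling, was higher in the same CD4 cells (median 0.54 over 16 genes, adjusted p = 0.0404, and adjusted p = 0.975 with an estimated correlation). The Gzmb UMIs lay in 13 cells with at most 35 in 1 cell. Xist, also among the 17 genes, had 102 UMIs in 19 cells of GA-aFuc mice. Of these mice 1 showed the female pattern, while the N297A mouse showed the male pattern. With a minimum of 5 CD4 cells per mouse, an alternative added after seeing the data, 0 genes passed by edgeR. Treg expression had no test, since library 2 held 24 annotated Tregs. These were 3 cells with 20351 UMIs in GA-aFuc mice, 2 with 11626 in GITR/Syn GA-aFuc mice, 8 with 68977 in the N297A mouse and 11 with 118415 in the Untreated mouse. In this order Ikzf2, the transcription factor Helios, had 2, 0, 265 and 159 UMIs, Areg, amphiregulin, 0, 0, 61 and 63, and Penk, proenkephalin, 0, 0, 59 and 5. Foxp3, the Treg lineage factor, was seen in 13 of 19 annotated Tregs of the N297A and Untreated mice and in 0 of 5 of the Fc-enhanced mice.

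N297A against Untreated, the agonist antibody without Fc binding, rested on 1 mouse per treatment in library 2, so its test assumes that these mice vary like the paired ones. Iigp1 was lower in dendritic cells of the N297A mouse (307 against 870 CPM, adjusted p = 0.0433). This call ended with the stricter filter on low counts (adjusted p = 0.0568) and with equal numbers of cells per mouse (-1.22, adjusted p = 0.188). In macrophages the interferon gamma list was lower (median -1.24 over 21 genes, 17 adjusted over the list alone, adjusted p = 2.16e-18, and adjusted p = 0.563 with an estimated correlation). Its members Cxcl9, a chemokine for T cells, and Iigp1 stood at -1.97 ± 0.66 and -1.58 ± 0.39, without passing over all genes. The MHC class II list was lower in the same cells (median -1.28 over 11 genes, 7 adjusted over the list alone, adjusted p = 3.61e-10), where H2-Aa, a class II chain, stood at -1.37 ± 0.39. None of the lists of this class went below adjusted p = 0.563 with an estimated correlation. Monocytes showed the interferon gamma list lower as well (median -0.54, 6 adjusted over the list alone, adjusted p = 4.86e-13, and adjusted p = 0.982 with an estimated correlation). Dendritic cells did too (median -0.57 over 20 genes, 1 over all and 4 adjusted over the list alone, adjusted p = 5.64e-07, and adjusted p = 0.596 with an estimated correlation). T cell transcripts were higher in the dendritic cells of the N297A mouse (median 2.77 over 5 genes, adjusted p = 0.0347, and adjusted p = 0.598 with an estimated correlation). CD8 T cells had a higher type I interferon list (median 0.58, adjusted p = 4.16e-06, and adjusted p = 0.663 with an estimated correlation). By edgeR 0 genes passed in monocytes (298 at an unadjusted p under 0.05, 4 by DESeq2), CD8 T cells (290, 1 by DESeq2) and macrophages (2.07% of genes at an unadjusted p under 0.05, 10 by DESeq2). The NK cells had 1 lower gene, the dendritic cells 2 and cDC2 alone 9 (2 by DESeq2).

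GITR/Syn GA-aFuc, the non-agonist antibody with the enhanced Fc part, was set against Untreated and against GA-aFuc. Against GA-aFuc, monocytes had lower Arg1 (-2.65 ± 0.27, adjusted p = 0.00343, 242 and 305 against 1181 and 2246 CPM) and Mrc1 (-2.76 ± 0.36, adjusted p = 0.0097). Lower as well were Pdcd1lg2 (-2.10 ± 0.24, adjusted p = 0.00343), Cdh1 (-2.85, adjusted p = 0.00343), Fabp5 (-1.55, adjusted p = 0.00459) and Ccl24 (adjusted p = 0.00626). F7, coagulation factor VII, was lower (-2.89 ± 0.44, adjusted p = 0.0275), as were Tarm1, an activating myeloid receptor (-1.71 ± 0.19, adjusted p = 0.00343), and Flt1 (69.6 and 71.2 against 132 and 150 CPM, adjusted p = 0.0474). Spint1, a protease inhibitor, was higher (1.18 ± 0.18, adjusted p = 0.0279). Flt1 was also the 1 gene called in macrophages (-1.95 ± 0.16, adjusted p = 0.0229; 9.74 and 11.5 against 41.8 and 40.5 CPM). In dendritic cells Cd209a, a lectin of cDC2 (-1.91, adjusted p = 0.0132), and Ctsl, a lysosomal protease (-1.72, adjusted p = 0.0467), were lower. So were Ccl4 (-1.41, adjusted p = 0.0129), Capg (-1.51, adjusted p = 0.0143), Lgals1, galectin 1 (-1.05, adjusted p = 0.0129), and S100a6 (-0.68, adjusted p = 0.0252). With equal numbers of cells per mouse 3 of these 6 calls were kept, while those of Ctsl (-1.09, adjusted p = 0.194), Ccl4 (-1.28, 0.14) and Capg (-0.91, 0.187) ended.

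The edgeR counts of GITR/Syn GA-aFuc against GA-aFuc were 1 higher and 12 lower in monocytes (603 at an unadjusted p under 0.05), 12 lower in dendritic cells and 1 lower in macrophages. Each of these treatments held 1 mouse with the female and 1 with the male pattern, and this fit does not include sex. With sex as a covariate the counts were far higher, as given with the processing settings. In cDC2 alone 8 genes were higher and 22 lower, with 6 by DESeq2. By edgeR there were 0 in CD8 T cells (311 at an unadjusted p under 0.05, 0 by DESeq2) and 0 in NK cells (411, 1 by DESeq2). Without monocyte cluster 42 the monocyte counts were 1 higher and 18 lower. Without GITR/Syn GA-aFuc replicate 2, 3 of the 10 monocyte genes named kept the call, with Arg1 at -2.49 (adjusted p = 0.218). Without replicate 3, 6 kept it. The macrophage Flt1 call ended without either (adjusted p = 0.136 and 0.371). The glycolysis and hypoxia list was lower in monocytes (median -0.34, 5 adjusted over the list alone, adjusted p = 6.81e-06, and adjusted p = 0.862 with an estimated correlation). Against Untreated, GITR/Syn GA-aFuc gave 0 genes by edgeR in monocytes (291 at an unadjusted p under 0.05, 2 by DESeq2), where Arg1 stood at 0.73 ± 0.33. By edgeR it gave 0 in macrophages (185 at an unadjusted p under 0.05, 0 by DESeq2), 0 in CD8 T cells (332, 0 by DESeq2) and 0 in dendritic cells (404, 0 by DESeq2). In cDC2 alone 2 genes were higher and 2 lower, with 0 by DESeq2. NK cells had 8 higher and 4 lower genes. The inflammatory list was higher in these monocytes (median 0.42, 4 adjusted over the list alone, adjusted p = 3.28e-05, and adjusted p = 0.985 with an estimated correlation). In CD8 T cells the list of macrophage transcripts, which marks RNA of other cells, was higher (median 1.16 over 8 genes, 4 adjusted over the list alone, adjusted p = 0.00114, and adjusted p = 0.52 with an estimated correlation). These cells also had a lower proliferation list (median -0.55, adjusted p = 7.04e-08, and adjusted p = 0.666 with an estimated correlation).

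NK cells and cDC2, and the contrast of both Fc-enhanced treatments against the other 2, were examined after the data were seen. In NK cells the granzymes Gzmd, Gzme and Gzmf and the interferon-induced Ifitm1 and Ifitm2 were higher in all 4 Fc-enhanced mice than in the N297A and Untreated mice. Gzmd and Gzme were among the leading genes of NK clusters 20 and 48. Whether a different mix of NK clusters accounts for these differences was not tested. Gzmd stood at 770, 826, 1506 and 940 CPM against 102 and 265 CPM (2.59 ± 0.18, adjusted p = 1.46e-06). Gzme rose by 3.19 ± 0.32 (adjusted p = 9.86e-05) and Gzmf by 5.60 ± 0.83 (adjusted p = 0.00861). Ifitm1 rose by 2.28 ± 0.17 (adjusted p = 2.8e-06) and Ifitm2 by 2.22 ± 0.14 (455, 501, 693 and 638 against 124 and 118 CPM, adjusted p = 6.21e-07). Oasl1, a type I interferon gene, fell by 1.29 ± 0.23 (adjusted p = 0.0225), Herc6 fell by 1.22 ± 0.19 (adjusted p = 0.00943) and Klra8 fell by 0.75 ± 0.13 (adjusted p = 0.0197). Granzyme B (Gzmb, 0.31, adjusted p = 0.54) and perforin (Prf1, 0.46, adjusted p = 0.202) did not pass. In all, 11 genes were higher and 14 lower of 9329. The type I interferon list was lower (median -0.63 over 23 genes, 1 over all and 14 adjusted over the list alone, adjusted p = 5.74e-11, and adjusted p = 0.814 with an estimated correlation). With equal numbers of cells per mouse, 4 of the 8 NK genes named kept the call, while Ifitm1 lay at 0.91 (adjusted p = 0.284), and the calls of Gzmf (0.0764), Oasl1 (0.0813) and Klra8 (0.319) ended as well. With the stricter filter on low counts 6 kept it, without Gzmf (adjusted p = 0.0633) and Oasl1 (0.0731), and without GITR/Syn GA-aFuc replicate 3 the call of Oasl1 ended (0.116).

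**Figure D3:**
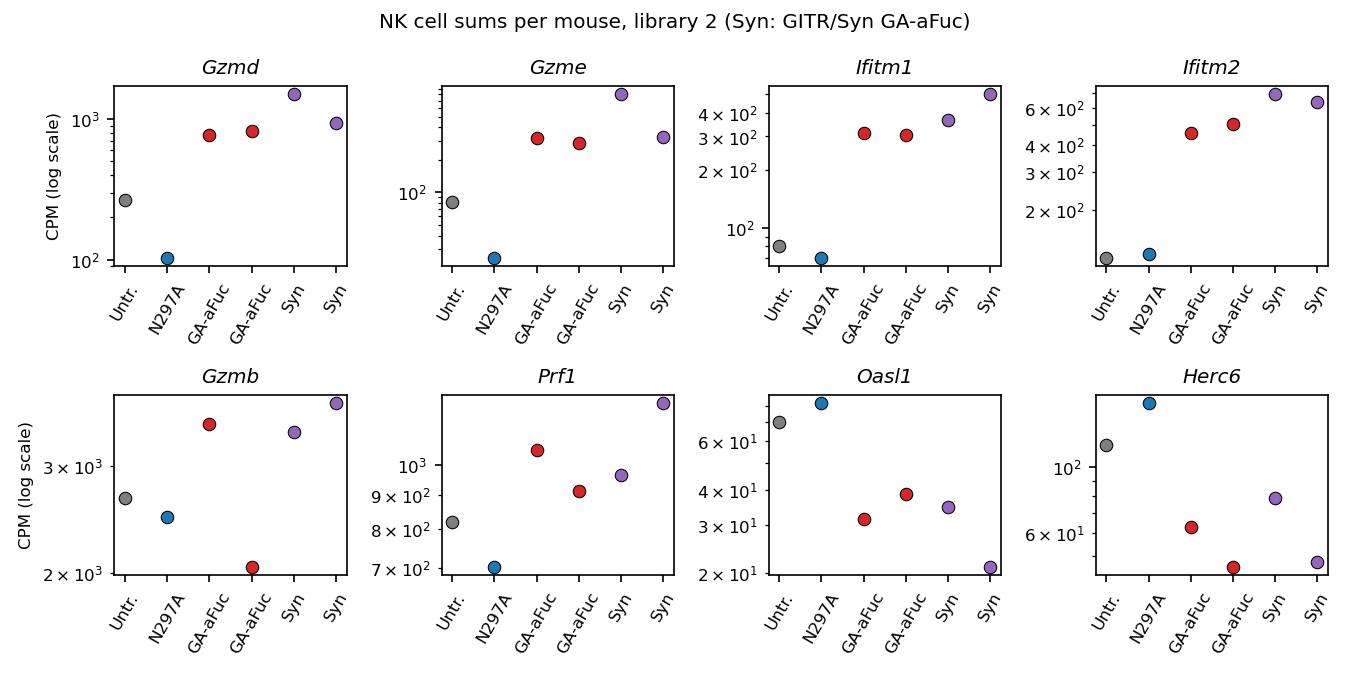
CPM (vertical axes, log scale) of Gzmd, Gzme, Ifitm1, Ifitm2, Gzmb, Prf1, Oasl1 and Herc6 in summed NK cells of the 6 mice of library 2, 1 point per mouse, coloured by treatment. Gzmd stands at 770 to 1506 CPM in the 4 mice given an Fc-enhanced antibody and at 102 and 265 CPM in the N297A and Untreated mice.

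In cDC2, the dendritic cells that present antigen mainly to CD4 T cells, Plet1 rose by 1.97 ± 0.27 (adjusted p = 0.000469) and Clec10a, a lectin of cDC2, by 1.48 ± 0.26 (adjusted p = 0.0039) in the 4 Fc-enhanced mice. In the same mice Pdcd1lg2 rose by 1.42 ± 0.25 (adjusted p = 0.0039) and Nrg1, neuregulin 1, by 3.04 ± 0.54 (adjusted p = 0.0041). The proliferation genes Mki67 (-1.61 ± 0.28, adjusted p = 0.0039), Top2a (-1.14 ± 0.22, adjusted p = 0.00731) and Rrm2 (-2.65 ± 0.51, adjusted p = 0.00743) were lower. Their list had a median of -0.87 over 19 genes (7 lower over all, 10 adjusted over the list alone, adjusted p = 7.11e-11, and adjusted p = 0.869 with an estimated correlation). By edgeR 18 genes were higher and 17 lower of 7404. With equal numbers of cells per mouse 3 of these 7 named genes kept the call. It ended for Mki67 (adjusted p = 0.273), Top2a (0.0671), Rrm2 (0.0512) and Pdcd1lg2 (0.128). DESeq2 kept 1 of the 7, and the stricter filter on low counts kept 0 of 5 tested, with Plet1 at 1.95 (adjusted p = 0.0757). The same filter gave 1 cDC2 gene, against 19, in GA-aFuc against Untreated, 0, against 42, in GA-aFuc against N297A and 8, against 30, in GITR/Syn GA-aFuc against GA-aFuc.

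Human Fcγ receptor transcripts were read from the same libraries and stood highest in myeloid cells. FCGR3B stood at 3491 ± 388 CPM in macrophages and 2932 ± 212 CPM in monocytes (SD, n = 6 mice), FCGR2A at 1046 ± 71.1 and 926 ± 156 CPM, and FCGR1A, the high-affinity receptor, at 227 ± 52.6 and 119 ± 28.1 CPM. FCGR2B, the inhibitory receptor, was highest in cDC2 (1345 ± 130 CPM) and monocytes (1129 ± 86.3 CPM), against 392 ± 92.5 CPM in macrophages. FCGR3A stood at 370 ± 49.9 CPM in macrophages, 69.1 ± 22.0 CPM in NK cells and 58.4 ± 26.2 CPM in CD8 T cells, and how much of the latter 2 values is free RNA of myeloid cells was not tested. FCGR3A UMIs were found in 34.9% of NK cells and 22.1% of CD8 T cells, at median depths of 8402 and 8505 UMIs. FCGR3A and FCGR3B, like FCGR2B and FCGR2C, are near-identical, so reads may be split between them and their separate levels are uncertain. Mouse Fcγ receptor transcripts were counted too. Fcgr2b stood at 431 ± 36.0 CPM in macrophages and 713 ± 57.6 CPM in monocytes (SD, n = 6). In the same cells Fcgr3 stood at 18.4 and 35.6 CPM, Fcgr1 at 0.223 and 0.518 CPM and Fcgr4 at 0.0112 and 0 CPM. GITR (Tnfrsf18) stood at 490 ± 169 CPM in CD4 T cells (n = 3 mice), 247 ± 30.3 CPM in CD8 T cells, and 109 ± 9.79 CPM in NK cells (n = 6). It stood at 36.8 ± 7.62 CPM in cDC2, at 1.83 ± 0.458 CPM in macrophages (n = 6) and at 789 CPM in the pooled 24 Tregs. Neither Tnfrsf18 nor an FCGR gene passed the edgeR test in any contrast and class tested. FCGR1A in monocytes of GA-aFuc against Untreated mice stood at -0.78 (adjusted p = 0.339).

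**Figure D4:**
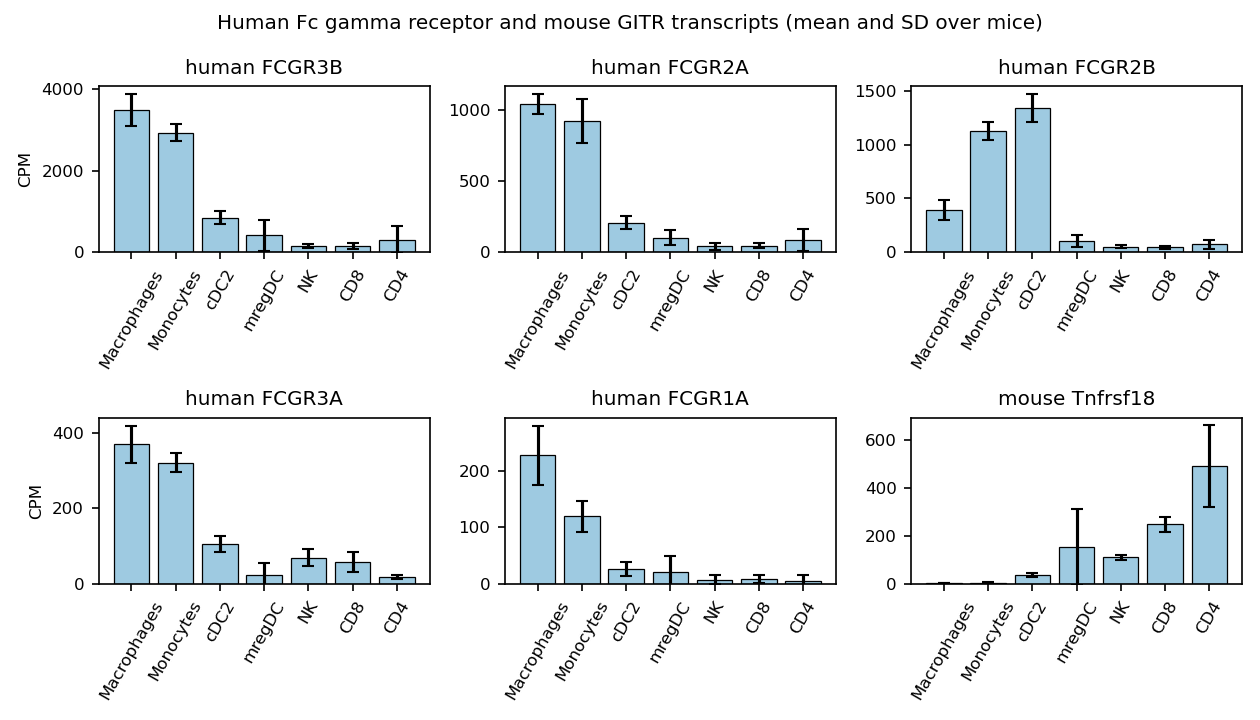
CPM (vertical axes) of 5 human FCGR genes and of mouse Tnfrsf18 in 7 cell types of library 2 (horizontal axes), with bars for the mean and whiskers for the SD over mice. FCGR3B averages 3491 CPM in macrophages and Tnfrsf18 averages 490 CPM in CD4 T cells.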

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

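Of the tests reported here, that of the monocyte cluster mix was set before its result was seen, and the others were chosen only after the results they bear on were seen.

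Fewer Tregs were annotated in mice given the Fc-enhanced antibodies. Tregs missed by the annotation are argued against as the whole cause. Among all library 2 barcodes with 1 dominant hashtag, those with Foxp3 and T cell UMIs were counted. Their percentage was 6.48 times higher in the N297A and Untreated mice (46 barcodes, 1.01%) than in the Fc-enhanced mice (14 barcodes, 0.156%). Per mouse it was 0.950% and 1.08% against 0.0427% to 0.276%. Of the 46 barcodes 28 lay outside the annotation, and of the 14 barcodes 10 did, so the annotation left out most such barcodes in both groups. A lower recovery of all T cells is argued against as well, since Tregs as a percentage of Tregs and CD4 cells differed 4.05 times, with no overlap between mice, and in library 2 without CD4 cells that carry Cd8a UMIs 3.16 times (at most 25% against at least 42.1%). A loss of Tregs that needs Fc receptor binding predicts fewer Tregs in GA-aFuc than in N297A mice. That difference passed by edgeR on cell counts (-2.68 ± 0.41 log2, SE, adjusted p = 0.000337). It also predicts no loss from Untreated to N297A mice, and these data leave that part open. The ratio of mean shares was 1.60, but 1.94 in library 1 and 0.718 in library 2. There the single N297A mouse (8 Tregs) lay below the single Untreated mouse (11 Tregs). The edgeR test of these 2 treatments did not pass (adjusted p = 0.313), so the explanation as a whole stays open. Differences between single tumours and the sort were not tested, and the males of library 2 alone showed 0.0649% and 0.0519% against 0.447% and 0.622%.

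Arg1, Mrc1 and other genes were higher in monocytes of GA-aFuc mice than of the Untreated mouse. A larger amount of macrophage RNA in monocyte droplets is argued against by the 8 listed macrophage transcripts, whose median log2 fold change was -0.47. An unchanged amount is not covered by this test. The 21 genes had positive log2 fold changes in macrophages too (median 2.05), so such RNA could carry the difference. Free RNA of the pool would add alike to all 6 mice that share it, but its test cannot decide. The lowest mouse had a median of 22.4% of the level of the lower GA-aFuc mouse over the 21 genes. These genes were called for lying lower in the Untreated mouse, which is among the mice searched for the lowest. A low percentage was thus fixed by their selection. A different mix of the authors' 15 monocyte clusters leaves a median log2 ratio of 2.13 over the 21 called genes once every mouse has the same mix, against 2.20 before. A difference of the 1 Untreated mouse alone is argued against. The same 21 genes had a median log2 fold change of 2.18 from N297A and 1.17 from GITR/Syn GA-aFuc to GA-aFuc mice. Of these genes 19 were higher in both GA-aFuc mice than in the 3 N297A and GITR/Syn GA-aFuc mice. The same 2 GA-aFuc mice enter these values, and the genes were called for being higher in them. Part of the size of these values may thus come from that selection. A response of monocytes to the agonist antibody with the enhanced Fc part stays open as a hypothesis from 2 GA-aFuc mice.

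By edgeR on cell counts CD4 cells were more frequent in GA-aFuc than in Untreated and GITR/Syn GA-aFuc mice, but not past the threshold against N297A mice or over the 4 treatments, and 17 genes differed between GA-aFuc and N297A mice. CD8 cells within the CD4 annotation could account for part of the frequency: without cells that carry Cd8a UMIs the ratio of GA-aFuc to GITR/Syn GA-aFuc shares in library 2 fell from 2.33 to 1.5, and shares then lay at 0.348% and 0.649% against 0.405% and 0.260%. The same cells bear on Gzmb, with 106 of its 145 UMIs in the 14 cells with Cd8a UMIs. Single cells could account for most of the gene calls, since 14 of the 17 genes had over 50% of the UMIs of the higher treatment in 1 cell. Sex could account for the call of Xist, since 1 GA-aFuc mouse showed the female and the N297A mouse the male pattern. A change of CD4 cells themselves was not separated from these.

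Signals outside the annotated comparisons were found among 3018 unannotated barcodes with 1 dominant hashtag and a median of 8695 UMIs. The mast cell gene Cpa3 had at least 10 UMIs in 110 of them and in 0 annotated cells. The fibroblast gene Col3a1 did so in 514 of them and in 1 annotated cell, although the sort for CD45 should leave fibroblasts out. The neutrophil gene S100a8 did so in 70 of them and in 8 annotated cells. Human transcripts other than the Fc receptors were also counted in annotated cells of library 2, with 32556 UMIs of ATF6, 27034 of DUSP12, 17291 of FCRLB, 2253 of FCRLA and 10811 of PLCG2.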

How the results depend on the processing

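The covariate for sex, the centred shares, the minimum of 5 CD4 cells, the classes without clusters led by other markers and all settings of the Fc-enhanced contrast were chosen only after the results were seen. Over results that answer a comparison, 230 values kept their side of the threshold or stayed within 1.5 times, 46 rose or newly passed, 21 fell or no longer passed and 6 moved by more than the spread, and none reversed; where a value is given without a cause, the cause was not tested. Genes called over 5 classes for GA-aFuc against Untreated numbered 27, with DESeq2 44, without a filter 622, with the stricter filter 13, without high-count cells 44, with equal cells 11, in a fit of these treatments alone 153, with sex 649, and 21 to 833 with 1 mouse left out, the highest without GA-aFuc replicate 2. For GA-aFuc against N297A they numbered 76, without a filter 806, in a fit of these treatments alone 344, with sex 622, and 65 to 725 with 1 mouse left out. For N297A against Untreated they numbered 3, with DESeq2 18, without a filter 188, with the stricter filter 1, without high-count cells 8, with equal cells 0 by edgeR, with sex 124, and 64 to 165 with 1 mouse left out. For GITR/Syn GA-aFuc against Untreated they numbered 12, with DESeq2 6, without a filter 189, with the stricter filter 3, with equal cells 2, in a fit of these treatments alone 186, with sex 157, and 12 to 145 with 1 mouse left out. For GITR/Syn GA-aFuc against GA-aFuc they numbered 26, with DESeq2 40, without a filter 598, with the stricter filter 16, without high-count cells 58, with sex 416, and 27 to 831 with 1 mouse left out. For the Fc-enhanced contrast they numbered 69, without a filter 694, with equal cells 34, with sex 560, and 159 to 653 with 1 mouse left out. Fits with sex or without 1 mouse of a pair keep 1 residual degree of freedom, and equal cells use fewer counts, by construction. The 17 CD4 genes became 0 with DESeq2, 9 with the stricter filter, 10 with equal cells and 0 with the minimum of 5 CD4 cells by edgeR. The adjusted p of the Treg share, 0.0111, was 0.246 without the library stratum, 0.222 in library 2 alone (the smallest possible there, so that it could not pass), 0.0914 with shares centred within libraries and 0.0111 to 0.175 with 1 mouse left out by the exact permutation test, and 0.000261 with edgeR. That of the macrophage share, 0.0654, was 0.0463 to 0.278 with 1 mouse left out by the exact test. Of 98 list calls in 595 tests, 0 passed with an estimated correlation (smallest adjusted p = 0.52). With 2 residual degrees of freedom per class that setting could hardly pass, so it does not decide about these lists. The fry test called 1 set moving one way and 9 in either direction. Thinning cells to 3000 UMIs lowered the percentage of cells with a UMI from 95.3% to 90.8% for FCGR3B in monocytes, 99.04% to 89.2% for FCGR2A in macrophages, 99.3% to 93.1% for FCGR2B in cDC2, 34.9% to 20.5% for FCGR3A in NK cells, and 55.9% to 27.4% for FCGR3B and 22.1% to 11.6% for FCGR3A in CD8 T cells. Of the results for the 79 named genes, counted per class and contrast, under settings with all mice, 722 kept the call and 108 missed the threshold; scaling moved the median of all genes by at most 0.0154 (log2). A fit of N297A and Untreated alone has no residual degree of freedom, leaving out either mouse ends that contrast, and own clustering and cell calling were not run because the deposited annotation was used. No label pairs the mice, since replicate numbers are an order of runs. Among fits of expression, only the one with sex as a covariate blocked mice. The edgeR fit of cell counts blocked them by library.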

Other observations

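The counts outside the annotation and of human transcripts were chosen after the data were seen, and the list tests were set before. Barcodes outside the annotation held transcripts of cell types that the annotation does not name, those of fibroblasts included, which a sort for CD45 should leave out. Besides Cpa3, the mast cell proteases Mcpt2 and Cma1 had at least 10 UMIs in 124 and 125 of the 3018 barcodes and in 0 annotated cells. The matrix proteoglycan gene Dcn, of fibroblasts, did so in 466 barcodes and in 0 annotated cells, while the T cell gene Cd3e did so in 12 barcodes and 106 annotated cells. S100a8 was found at that level in 51 of the 638 such barcodes of 1 GA-aFuc mouse and in 2 to 6 barcodes of each of the other 5 mice. Cpa3 was spread more evenly, with 12 to 25 barcodes per mouse.

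Human FCRLA stood at 684 CPM in pDC and at 20.9 CPM in macrophages, 9.70 CPM in monocytes and 1.28 CPM in CD8 T cells. The human HSPA6, a heat-shock gene, had 159 UMIs in CD4 cells of GA-aFuc mice, all in 1 cell.

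No list call passed with an estimated correlation, a setting that could hardly pass with the few residual degrees of freedom here. Over 5 classes and 5 contrasts, gene lists passed camera at its preset correlation as follows. Interferon gamma response passed 15 times, type I interferon response 12, glycolysis and hypoxia 9, proliferation 9, MHC class II 8, inflammatory cytokines and chemokines 7, T cell transcripts 7, TCR activation 6, tumour-associated macrophage 5, naive and memory T cell 4, phagocytosis and lysosome 4, MHC class I 3, cytotoxicity 2, macrophage transcripts 2, and DC maturation, GITR and costimulation, human Fc gamma receptors, mitochondrial transcripts and Treg program 1 each. The other 7 of 26 lists passed in 0 classes by camera: B and plasma cell transcripts, dissociation stress, exhaustion, mouse Fc receptors, neutrophil transcripts, stromal and tumour transcripts, and Th1 and CD4 effector genes. CD4 cells are not among these 5 classes, and in GA-aFuc against N297A they had dissociation stress and inflammatory cytokines and chemokines past camera (adjusted p = 0.0404 for each, and adjusted p = 0.975 with an estimated correlation).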
